A study of Homo sapiens with 4 samples.

How the data were processed

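RNA was taken from cells differentiated from the human embryonic stem cell line H1 with an eGFP reporter in GATA2 (all titles also name Cre, without a role), sorted into a GFP-positive and a GFP-negative fraction. Per the labels' protocols, RNA was harvested with Trizol and libraries were made from total RNA with an Illumina TruSeq RNA kit. There were 4 libraries, 2 of each fraction. Groups, by presence or absence of GFP, and replicate numbers came from the sample titles.

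The authors deposited 1 table per library, and per the file headers each holds an Ensembl gene identifier, a gene symbol and a TPM value, which scales a gene's reads by transcript length and library total. The submitters' processing notes name Bowtie and RSEM, without versions, and the genome builds hg19 and mm10, without saying what each was used for. The annotation and the parameters are not given in the sources used here. All 4 tables hold the same 28285 rows in the same order, and TPM sums lie between 996323.64 and 997292.9. The tables have 0 rows for mitochondrially encoded genes, 0 for ribosomal proteins with RPL or RPS and a number as symbol, 0 for eGFP and 0 for PECAM1; these genes are not analysed here. Of the identifiers, 25364 (89.7%) matched GENCODE v29 on GRCh38, from which gene class and the printed gene coordinates were taken. There were 87 repeats of a symbol, and for a named gene the row was taken whose identifier a table of gene names pairs with the symbol, otherwise the row with the highest mean.

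The choice of test, lists and naming rule was made before the data were examined. A test on counts had been planned as the first choice, and limma on log2 values as the choice where only TPM was given. Because the deposited values are TPM, limma 3.58.1 in R 4.3.3 was used on log2(TPM + 1), with a variance trend, for genes with at least 1 TPM in at least 2 of the 4 libraries. P-values were two-sided and adjusted by Benjamini-Hochberg, with 0.05 as the threshold. Fold changes on this scale understate the change of low genes. In 20 simulations of 15425 genes, changes were put only into the more abundant genes. Limma recovered 1.55% of genes changed by a log2 fold of 1 and 42.3% of those changed by 2. All recovered genes had the right sign, and 4.47% of calls were false. Many differences of this size would therefore not be called with 2 libraries per fraction. Simulated values were independent and drawn from the variances that limma had fitted. A false share near the threshold was thus built in and does not describe the calls in these data.

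Gene lists, 22 in all, covered blood, endothelial and signalling genes (10 main lists) and cell types or states that the sorted cells could hold (12 background lists). Of these, 20 had at least 3 measured members and were tested with camera, which compares a list with all other genes, with a preset correlation of 0.01 between genes. The estimated correlation and fry, which asks whether a list's genes move one way on balance, were set beside it. Camera p-values were adjusted over the lists by Benjamini-Hochberg. In the simulations, camera called 20 of 20 shifted lists of 30 genes and 0 of 20 lists left as they were. Simulated genes varied independently, so this does not show how camera behaves where genes of a list are correlated. In the data, the estimated correlation of the called lists ran from -0.0215 for Notch pathway genes to 0.254 for HOX genes. Arterial genes, estimated at -0.0169 and so below the preset, also lost their call (camera adjusted p = 0.000462 with the preset, 0.254 with the estimate). With an estimated correlation, camera also uses the few degrees of freedom that 4 libraries leave. A call lost this way therefore does not by itself show that correlated genes had produced it. Some lists share members.

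Genes were named by this rule: GATA2, RUNX1, CD34, PECAM1 and SPN; the 5 largest rises and 5 largest falls among called genes with a mean of at least 10 TPM in the higher fraction and no overlap between fractions, leaving out XIST, Y-linked genes and rows without a symbol; and the 3 members of each main list and the 1 member of each background list with the smallest p. Other genes named were chosen after their values were seen.

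Read totals cannot be had from TPM. Where a gene has a single annotated transcript of over 1500 nt, the product of TPM and length fell in steps. Of low values, 65.9% to 68.3% lay within 0.15 of a whole step, against 30% for evenly spread values. The step was fitted to these same values, so part of the excess near the first step was built in. If a step is a read, a gene of 10 TPM with a 2 kb transcript had 30.7 and 19.9 reads in GFP-positive replicates 1 and 2, and 33.5 and 27.1 in GFP-negative replicates 1 and 2. Values of a few TPM therefore rest on few reads, most of all in GFP-positive replicate 2. The top 10 genes held 6.95% to 7.61% of TPM.

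Alternatives tried were another pseudocount, no filter, the replicate number as a block and each library left out in turn. Added after seeing the data were scaling by the median of ratios and by the upper quartile, a filter on mean TPM above 5, no variance trend, and protein-coding rows only. Other tests and filters, which need read counts, were not run. A fit with a library left out has fewer samples to estimate variance. Adjusted p-values near the threshold can then rise without a single library having driven the difference. Figures were drawn with matplotlib 3.10.9.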

Results

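RNA sequencing compared a pair of sorted cell fractions made from H1, an established human embryonic stem cell line. A reporter, enhanced green fluorescent protein (eGFP), had been knocked into GATA2, which encodes a zinc-finger transcription factor of blood stem and progenitor cells. Both fractions were sorted for the surface proteins CD34 and CD31 and for absence of CD43, a sialoglycoprotein of blood cells. The fraction with eGFP is called GFP-positive here, and its cell type was given as hemogenic endothelium, the endothelium from which blood cells emerge. The fraction without eGFP is called GFP-negative, and its cell type was given as endothelial cells. The titles and source names of all 4 samples, however, carry hemogenic endothelium or its initials, so the labels differ on what the GFP-negative cells were. All titles also name Cre, whose use the labels do not explain. Each fraction had 2 libraries, and errors of single genes are an SD over n = 2 or a standard error (SE) of a limma fit over all 4 libraries.

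Levels were given as TPM, a gene's length-corrected share of all transcripts scaled to a fixed total, for 28285 gene rows. In the GFP-positive libraries, 14804 and 14730 genes reached 1 TPM, against 15109 and 15062 in the GFP-negative libraries. Read totals are unknown, because TPM keeps no depth. If a step between low values is a read, relative depths were 0.916 and 0.595 for GFP-positive replicates 1 and 2. They were 1 and 0.808 for GFP-negative replicates 1 and 2. Across genes, Pearson's correlation of log2(TPM + 1) was 0.926 between the GFP-positive libraries and 0.939 between the GFP-negative libraries, against 0.904 to 0.921 between libraries of different fractions. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels of PECAM1, the gene of CD31, of eGFP and of the mitochondrially encoded genes are not analysed here.

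The comparison asked how the transcriptomes of cells with and without the reporter differ. GATA2 was 4.10-fold higher in GFP-positive cells, and GFI1, a zinc-finger repressor of early blood development, was 5.18-fold higher. Genes of the endothelial cell type were lower in GFP-positive cells as a group, with a median log2 fold change of -1.10 over 38 measured genes, of which 10 fell and 28 did not pass. Erythroid genes were higher as a group, with a median of 2.22 over 18 measured genes, of which 1 rose and 17 did not pass. Camera, limma's test of a gene list against all other genes, called both lists with its preset correlation (adjusted p = 1.67e-26 and 1.30e-11) and neither with an estimated one (adjusted p = 0.254 with an estimated correlation for each). CD34 fell in GFP-positive cells, to 497 TPM against 1215 TPM. Of 15425 genes tested with limma, 69 passed a Benjamini-Hochberg adjusted p of 0.05, 19 higher and 50 lower in GFP-positive cells, and 2171 had an unadjusted p under 0.05. Among the 69 genes, 51 were protein-coding, of which 13 were higher and 38 lower. The smallest adjusted p was 0.0316, and every one of the 69 had an absolute log2 fold change above 1, on a log2(TPM + 1) scale that understates changes of low genes.

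These calls lie close to the threshold: limma called 0 genes with a pseudocount of 0.1 (2101 at an unadjusted p under 0.05), 0 without the filter on low values (2230) and 0 without a variance trend (2072). With a library left out, limma called 58 genes (10 higher, 48 lower) without GFP-positive replicate 1 and 53 (12 higher, 41 lower) without GFP-positive replicate 2. The balance turned to more higher than lower calls without either GFP-negative library, with 18 genes (17 higher, 1 lower) without replicate 1 and 65 (36 higher, 29 lower) without replicate 2. There were 9 genes that passed with every library left out in turn: GATA2, GFI1, KEL, HBG2, H19, MYL4, MT2A and FGFBP3, which were higher in GFP-positive cells, and RAMP2, which was lower.

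GATA2 (ENSG00000179348; GENCODE v29 on GRCh38, chromosome 3, 128479427 to 128493185, minus strand) carries the reporter by which the cells were sorted, so its level and the sort are not independent. It stood at 343 ± 58.2 TPM (SD, n = 2) in GFP-positive cells and 83.7 ± 5.03 TPM in GFP-negative cells, a log2 fold change of 2.01 ± 0.17 (SE; limma adjusted p = 0.0316). RUNX1, a transcription factor required for blood cells to emerge from endothelium, had 263 ± 91.6 TPM against 115 ± 26.5 TPM. Its log2 fold change of 1.16 ± 0.28 did not pass (limma adjusted p = 0.159). Both GFP-positive libraries lay above both GFP-negative libraries. Such separation, in either direction, was common, at 44.3% of all tested genes against 33.3% by chance. SPN, the gene of CD43, had 13.6 ± 4.71 TPM against 10.4 ± 0.983 TPM, with overlapping libraries and a log2 fold change of 0.32 ± 0.39 (limma adjusted p = 0.787).

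Among 28 measured hematopoietic transcription factors, 4 rose, 0 fell and 24 did not pass. Adjusted over the list alone, 11 rose and 5 fell. GFI1 rose from 25.7 to 133 TPM (log2 fold change 2.33 ± 0.18, SE; limma adjusted p = 0.0316). NFE2, a factor of erythroid and megakaryocytic cells, rose from 5.67 to 50.5 TPM (2.92 ± 0.33; limma adjusted p = 0.0403). MYB, a factor of definitive blood progenitors and chosen after its values were seen, was the fourth, at 59.1 against 10.9 TPM (limma adjusted p = 0.0439). Without GFP-positive replicate 1, limma gave NFE2 and MYB adjusted p-values of 0.0767 and 0.0785, without GFP-positive replicate 2 0.0501 and 0.0808, and without GFP-negative replicate 1 0.0707 and 0.0641; without GFP-negative replicate 2, NFE2 passed and MYB had 0.0535. Of the 28, 17 were above 0 and 11 below. Other factors of the list, also chosen after their values were seen, differed in direction, and none of them passed. Log2 fold changes near or below 0 were those of TAL1 (-0.54), LMO2 (-0.15), FLI1 (-0.29), GFI1B (0.12) and MYCN (-1.26). Well above 0 were those of SPI1 (1.69), CBFA2T3 (1.47) and GATA1 (2.71). The list as a whole had a median log2 fold change of 0.15 and missed the threshold in camera (adjusted p = 0.0571, and adjusted p = 0.637 with an estimated correlation). Camera called it without a filter (adjusted p = 0.0488), with upper quartile scaling (0.0471), with a mean above 5 TPM (0.0279), without GFP-positive replicate 2 (0.0394) and without GFP-negative replicate 1 (0.000692), while its median ran from -0.03 without GFP-negative replicate 2 to 0.35 without GFP-negative replicate 1, with 0.27 without GFP-positive replicate 1.

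Of 34 measured hematopoietic surface and signalling genes, 1 rose and 1 fell, and adjusted over the list alone 6 rose and 1 fell. ARHGDIB, a gene abundant in blood cells, rose from 298 to 677 TPM (log2 fold change 1.18 ± 0.12, SE; limma adjusted p = 0.039). KIT, the stem cell factor receptor, fell from 36.2 ± 0.636 to 6.30 ± 0.191 TPM (SD, n = 2; log2 fold change -2.35 ± 0.30; limma adjusted p = 0.0483). Neither gene passed in limma with any library left out. Such fits have fewer samples to estimate variance, so this does not show that a single library drove either difference. PTPN6, a phosphatase of blood cell signalling, had 52.4 against 19.9 TPM and did not pass (limma adjusted p = 0.0953). The list, with a median log2 fold change of 0.25, was not called by camera (adjusted p = 0.0955, and adjusted p = 0.611 with an estimated correlation). It was called with a mean above 5 TPM (camera adjusted p = 0.035) and without GFP-positive replicate 1 (0.0301), and its median was 0.03 without GFP-positive replicate 2, 0.01 without GFP-negative replicate 2 and 0.13 without a filter.

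**Figure D1:**
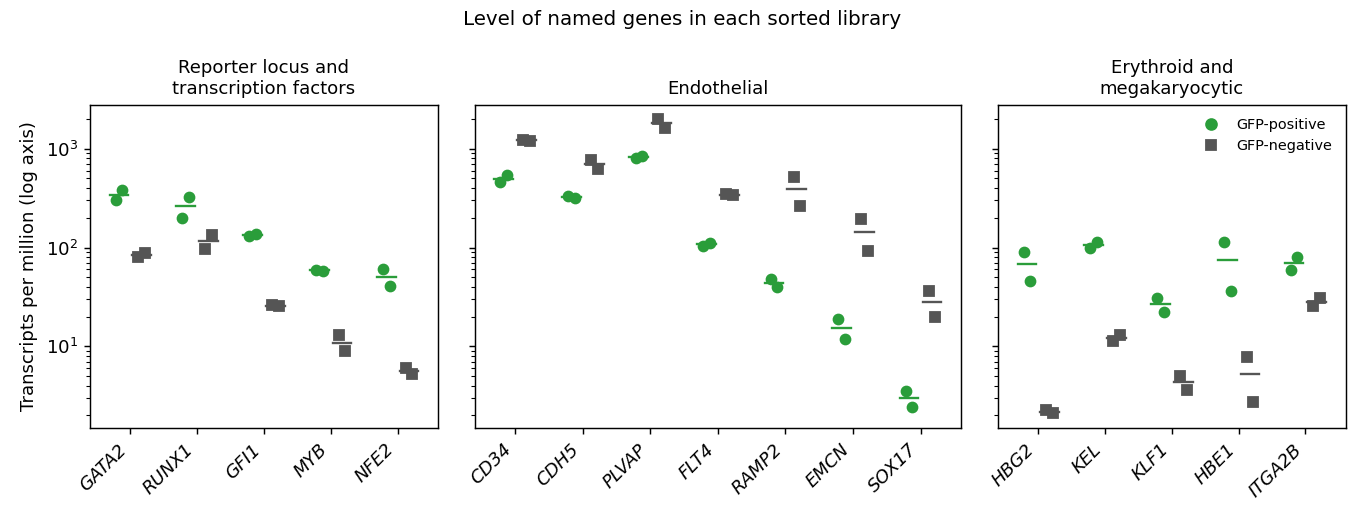
Level of named genes in each library, in TPM on a log axis, for the reporter locus and transcription factors, endothelial genes, and erythroid and megakaryocytic genes. Circles are the 2 GFP-positive libraries, squares the 2 GFP-negative libraries and short lines their means; GATA2 lies at 302 and 385 TPM in the GFP-positive libraries and at 80.2 and 87.3 TPM in the GFP-negative libraries, while CD34 is lower in the GFP-positive libraries.

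All 38 measured pan-endothelial genes had a log2 fold change below 0, also under both other scalings, with values from -3.41 to -0.03. Of these, 10 fell, 0 rose and 28 did not pass, and adjusted over the list alone 30 fell. CD34, a surface sialomucin of endothelium and blood progenitors, fell from 1215 ± 23.0 to 497 ± 54.7 TPM (SD, n = 2; log2 fold change -1.29 ± 0.13, SE; limma adjusted p = 0.0316). RAMP2, a co-receptor for adrenomedullin, fell from 388 to 44.0 TPM (-3.03 ± 0.32; limma adjusted p = 0.0391), and ARHGEF15 from 106 to 17.7 TPM (-2.50 ± 0.27; limma adjusted p = 0.0391). Endothelial genes chosen after their values were seen ranged widely. CDH5, the gene of VE-cadherin, had 322 against 695 TPM and did not pass (limma adjusted p = 0.0524), and KDR, a receptor for vascular endothelial growth factor, had 636 against 1024 TPM (limma adjusted p = 0.0878). MCAM had 336 against 343 TPM, and ICAM2 had 349 against 380 TPM. Camera called the list lower (adjusted p = 1.67e-26), a call that is lost at adjusted p = 0.254 with an estimated correlation. Without GFP-negative replicate 1, limma gave CD34 an adjusted p of 0.0908 and ARHGEF15 one of 0.112, and without GFP-positive replicate 1 it gave CD34 0.0504.

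Venous and lymphatic endothelial genes were lower as a list, with a median log2 fold change of -0.75 over 13 measured members (camera adjusted p = 9.84e-05, and adjusted p = 0.254 with an estimated correlation). Of the 13, 1 fell and 12 did not pass, and adjusted over the list alone 7 fell. Members lay on both sides, 9 below 0 and 4 above. Of those below 0, 3 (VWF, TEK and EMCN) are also on the pan-endothelial list. Those above 0 were PROX1 (log2 fold change 0.70), CCL21 (1.04), PDPN (1.23) and NR2F1 (0.15), none of which passed. FLT4, a lymphatic receptor for vascular endothelial growth factor, fell from 343 ± 5.13 to 108 ± 5.14 TPM (SD, n = 2; log2 fold change -1.67 ± 0.14, SE; limma adjusted p = 0.0316, and 0.0641 without GFP-negative replicate 1). EMCN, the gene of the sialomucin endomucin, had 15.4 against 143 TPM (limma adjusted p = 0.0519), and NT5E, the gene of the ectonucleotidase CD73, had 7.06 against 66.6 TPM (limma adjusted p = 0.058).

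Arterial endothelial genes had a median log2 fold change of -0.59 over 25 measured members, none of which passed over all genes, while 10 fell when adjusted over the list alone (camera adjusted p = 0.000462, and adjusted p = 0.254 with an estimated correlation). SOX17, a transcription factor of arterial endothelium, had 2.98 ± 0.75 TPM in GFP-positive cells and 28.1 ± 11.4 TPM in GFP-negative cells (SD, n = 2; limma adjusted p = 0.0666). Notch pathway genes, of which 8 were shared with the arterial list, had a median of -0.36 over 30 members. None of them passed over all genes, and adjusted over the list alone 1 rose and 8 fell (camera adjusted p = 0.00111, and adjusted p = 0.254 with an estimated correlation). The Notch median was -0.24 without GFP-positive replicate 1 and -0.17 without GFP-negative replicate 2. In both lists, HEY1, a transcriptional target of Notch, had 40.8 against 120 TPM (limma adjusted p = 0.0756), and the receptor gene NOTCH4 had 16.5 against 49.6 TPM (limma adjusted p = 0.114). LFNG, a glycosyltransferase that modifies Notch, had 51.1 against 127 TPM (limma adjusted p = 0.0827).

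BMP and TGF-beta signalling genes had a median log2 fold change of -0.44 over 33 measured members (camera adjusted p = 0.0145, and adjusted p = 0.254 with an estimated correlation). Of these, 0 rose, 2 fell and 31 did not pass, and adjusted over the list alone 1 rose and 5 fell. The 2 that fell were targets of BMP signalling, ID3 from 644 to 269 TPM (-1.26 ± 0.14, SE; limma adjusted p = 0.0403) and ID1 from 416 to 187 TPM (-1.15 ± 0.13; limma adjusted p = 0.0413). ENG, an endothelial co-receptor of the TGF-beta family, had 92.1 against 199 TPM and did not pass (limma adjusted p = 0.0848). Members also went the other way, with 11 of the 33 above 0. Chosen from these after their values were seen, ID2, of the family of ID1 and ID3, had 414 against 242 TPM (limma adjusted p = 0.107). SMAD6, likewise chosen afterwards, had 227 against 164 TPM (limma adjusted p = 0.324). Camera did not call the list without GFP-positive replicate 1 (adjusted p = 0.0504) or without GFP-negative replicate 2 (adjusted p = 0.123), where its median was -0.21, and the median was -0.17 with a mean above 5 TPM. With each library left out, limma gave ID1 adjusted p-values of 0.0597 to 0.121, and ID3 missed at 0.0582 without GFP-positive replicate 1 and at 0.117 without GFP-negative replicate 1.

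HOX genes had a median log2 fold change of -1.15 over 13 measured members, 12 of them below 0 (camera adjusted p = 0.00018, and adjusted p = 0.404 with an estimated correlation). None passed over all genes, and adjusted over the list alone 3 fell. HOXA9, a HOX gene of blood stem and progenitor cells, had 1.91 ± 0.099 TPM in GFP-positive cells and 12.2 ± 0.0212 TPM in GFP-negative cells (SD, n = 2; log2 fold change -2.19 ± 0.42, SE; limma adjusted p = 0.102). HOXC10 was listed at 0 in both GFP-positive libraries and at 4.26 and 2.87 TPM in the GFP-negative libraries, and HOXB9 had 36.0 against 80.7 TPM. The size of the median depended on the setting, in both directions. It was -1.54 without GFP-positive replicate 1 and -0.72 without GFP-positive replicate 2. It was -0.70 without GFP-negative replicate 1 and -0.39 without GFP-negative replicate 2. Without a filter it was -0.51, and with a mean above 5 TPM it was -0.33. Camera called the list in each of these settings.

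Extracellular matrix and adhesion genes had a median log2 fold change of -0.17 over 42 measured members, with members on both sides (camera adjusted p = 0.00857, and adjusted p = 0.611 with an estimated correlation). None passed over all genes, and adjusted over the list alone 6 rose and 13 fell. FN1, the gene of fibronectin, had 260 against 596 TPM (limma adjusted p = 0.0519), and HSPG2, the gene of the basement membrane proteoglycan perlecan, had 143 against 401 TPM (limma adjusted p = 0.058). ITGB3, an integrin subunit of platelets and endothelium, had 30.1 against 5.24 TPM (limma adjusted p = 0.0541). The list was not called without GFP-positive replicate 1 (median -0.06; camera adjusted p = 0.128) or without GFP-negative replicate 2 (-0.11; camera adjusted p = 0.251), and its median was -0.41 without GFP-positive replicate 2 and -0.31 without GFP-negative replicate 1.

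Erythroid genes were higher in GFP-positive cells as a list, with a median log2 fold change of 2.22 over 18 measured members (camera adjusted p = 1.30e-11, and adjusted p = 0.254 with an estimated correlation). All 18 were above 0, and 17 of them under upper quartile scaling; without a filter on low values the list's median was 1.27. Of the 18, 1 rose and 17 did not pass, and adjusted over the list alone 12 rose. HBG2, a fetal gamma-globin gene, rose from 2.19 ± 0.113 to 68.1 ± 31.8 TPM (SD, n = 2; log2 fold change 4.36 ± 0.42, SE; limma adjusted p = 0.0316). Its split from the near-identical HBG1 is uncertain, as is that between HBA1 and HBA2, because such near-identical genes can share reads. KLF1, a transcription factor of red cell genes chosen after its values were seen, had 26.7 against 4.36 TPM (limma adjusted p = 0.069), and HBE1, the embryonic epsilon-globin gene, had 74.4 against 5.30 TPM (limma adjusted p = 0.0959). KEL, the gene of a red cell surface antigen outside the list and also chosen afterwards, rose from 12.1 to 106 TPM (3.03 ± 0.23; limma adjusted p = 0.0316).

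Megakaryocyte and platelet genes had a median log2 fold change of 0.84 over 22 measured members (camera adjusted p = 0.000333, and adjusted p = 0.254 with an estimated correlation). The median was 0.23 without a filter on low values. NFE2 rose, 21 did not pass, and adjusted over the list alone 8 rose and 1 fell. ITGA2B, the gene of CD41, had 69.4 against 28.2 TPM (limma adjusted p = 0.104), and CMTM5 had 49.2 against 9.37 TPM (limma adjusted p = 0.0541); both were chosen after their values were seen. Myeloid, mast cell and macrophage genes were not called, with a median of -0.09 over 13 measured members and camera's direction upward (camera adjusted p = 0.893). Their median was 0.18 without GFP-positive replicate 1, -0.22 without GFP-positive replicate 2 and 0.33 with a mean above 5 TPM, and 10 of the 13 lay below 10 TPM in both fractions. HDC, the histidine decarboxylase gene, had 2.79 against 0.28 TPM (limma adjusted p = 0.277).

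**Figure D2:**
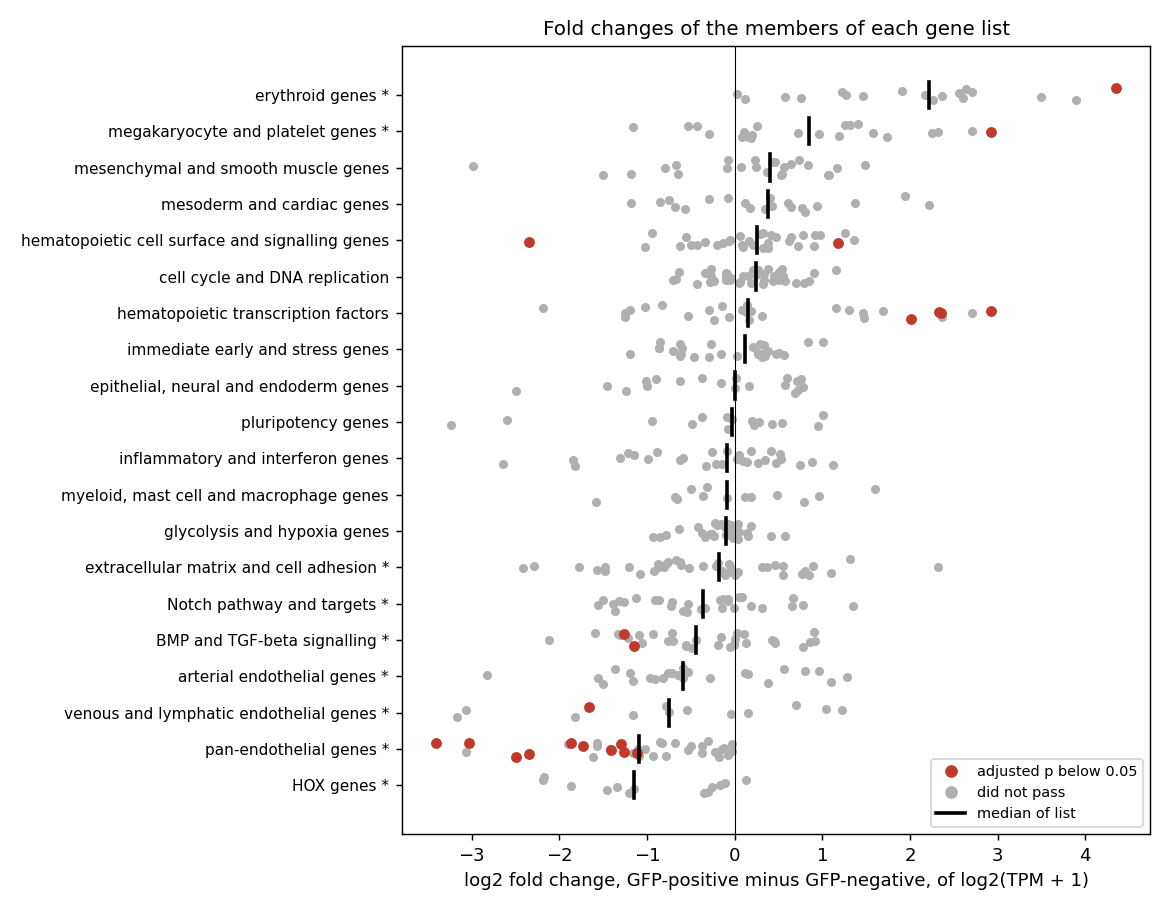
Log2 fold change, GFP-positive minus GFP-negative, of log2(TPM + 1) for each measured member of the 20 tested gene lists; each point is a gene, red where its limma adjusted p was under 0.05, and bars are list medians. Lists with an asterisk were called by camera with its preset correlation; erythroid genes lie to the right, with a median of 2.22, and pan-endothelial genes to the left, with a median of -1.10.

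Cell cycle and DNA replication genes narrowly missed the threshold in camera (median log2 fold change 0.25 over 43 measured members; adjusted p = 0.054, and adjusted p = 0.581 with an estimated correlation). Camera called the list upward without a filter (adjusted p = 0.019), without GFP-positive replicate 2 (0.00363) and without GFP-negative replicate 1 (0.0328), and its median was 0.15 without GFP-positive replicate 1 and 0.16 without GFP-negative replicate 2. None passed over all genes, and adjusted over the list alone 2 rose and 1 fell. CCND3, the gene of cyclin D3, had 234 against 106 TPM (limma adjusted p = 0.0899). CDKN1C, a cyclin-dependent kinase inhibitor, had 213 against 115 TPM (limma adjusted p = 0.103), and MCM5, a subunit of the replicative helicase, had 139 against 227 TPM (limma adjusted p = 0.12).

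Markers of other cell types that a differentiated culture can hold were not called as lists over all 4 libraries with the main filter. Mesenchymal and smooth muscle genes had a median log2 fold change of 0.40 over 24 members (camera adjusted p = 0.15), and mesoderm and cardiac genes one of 0.38 over 20 (camera adjusted p = 0.484). Mesenchymal and smooth muscle genes were called higher with a mean above 5 TPM (camera adjusted p = 0.0237), without GFP-positive replicate 2 (0.0375) and without GFP-negative replicate 2 (0.00805), and had a median of 0.20 without GFP-positive replicate 1. Over all libraries this list had adjusted p = 0.611 with an estimated correlation. The mesoderm and cardiac median ran from 0.16 without GFP-positive replicate 1 to 0.57 without GFP-positive replicate 2. Adjusted over the list alone, 3 and 2 of the mesenchymal and mesodermal genes rose and 2 and 3 fell. FOXC1 was listed at 0 and 0.28 TPM in the GFP-positive libraries and at 8.96 and 7.06 TPM in the GFP-negative libraries, and MEF2C had 53.7 against 122 TPM (limma adjusted p = 0.0674). Pluripotency genes had a median of -0.03 over 15 members (camera adjusted p = 0.977; 2 fell when adjusted over the list alone), and one of 0.07 to 0.31 with each library left out. Among them, POU5F1 had 0.48 against 7.78 TPM (limma adjusted p = 0.131). Epithelial, neural and endoderm genes had a median of 0.00 over 19 members, whose sign turned negative under both other scalings, and a mean of -0.22 (camera adjusted p = 0.977; 2 rose and 1 fell when adjusted over the list alone). The median ran from -0.35 without GFP-positive replicate 2 to 0.29 without GFP-positive replicate 1, and was 0.64 with a mean above 5 TPM (camera adjusted p = 0.0644). Of these, APOA1 had 7.92 against 50.8 TPM (limma adjusted p = 0.0541).

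The stress, interferon and glycolysis lists were not called by the main test over all 4 libraries. Immediate early and stress genes had a median log2 fold change of 0.12 and a mean of -0.07 over 28 members, with camera's direction downward (camera adjusted p = 0.89). Their median was -0.08 without GFP-positive replicate 2, -0.04 without GFP-negative replicate 1 and 0.02 without GFP-positive replicate 1 or without a filter. Inflammatory and interferon genes had a median of -0.09 over 29 (camera adjusted p = 0.484). With each library left out, it ran from -0.21 without GFP-positive replicate 1 to 0.03 without GFP-positive replicate 2. With a mean above 5 TPM, the median was 0.05. Glycolysis and hypoxia genes had one of -0.10 over 29 (camera adjusted p = 0.136). The glycolysis list was called lower without GFP-positive replicate 1 (median -0.21; camera adjusted p = 0.0181) and without GFP-negative replicate 2 (-0.20; 0.0024), and its median was 0.02 with either of the other libraries left out; over all libraries the list had adjusted p = 0.724 with an estimated correlation. None of the members of these lists passed over all genes or adjusted over the list alone. IER2 had 188 against 338 TPM (limma adjusted p = 0.122), OAS2 had 0.39 against 7.90 TPM (limma adjusted p = 0.104) and PFKP had 487 against 326 TPM (limma adjusted p = 0.115). Of the ribosomal protein list, 2 genes were measured, so no list test was made, and FAU had 1020.2 against 1139 TPM (limma adjusted p = 0.597).

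By fold alone, the called genes furthest apart were rows whose identifiers GENCODE v29 does not hold, several of them with microRNA symbols. AC004895.1 had 48.0 and 174 TPM, MIR4751 had 61.6 and 104 TPM and AC114969.1 had 61.7 and 74.4 TPM in the GFP-positive libraries, and all were listed at 0 in both GFP-negative libraries, as were AC111194.1 and AL118525.1. In the other direction, AP000765.1 had 277 and 102 TPM, MIR3615 had 56.3 and 18.4 TPM, AC091038.1 had 29.5 and 28.7 TPM and MIR631 had 37.3 and 21.6 TPM in the GFP-negative libraries, and all were listed at 0 in both GFP-positive libraries. AL117337.1 had 66.2 and 412 TPM in GFP-negative cells against 0 and 0.67 TPM. A value of 0 in these files can be a failed estimate, so no fold is given. Of the 69 called genes, 15 were listed at 0 throughout a fraction, and none of those 15 was annotated as protein-coding.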

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

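Scaling by the median of ratios or the upper quartile, a mean above 5 TPM, no variance trend and protein-coding rows were chosen after seeing the data. All 69 genes that passed kept their sign wherever they were tested, in every setting run, and the 9 lists called kept their direction. Every setting reuses the 4 libraries from which these genes and lists were called, so the kept signs are not independent support. The count of genes past the threshold fell to 0 (0 higher and 0 lower) with a pseudocount of 0.1, with smallest limma adjusted p = 0.0638 and 2101 genes at an unadjusted p under 0.05, to 0 without a filter (0.0612; 2230) and to 0 without a variance trend (0.0736; 2072). It rose to 164 (50 higher, 114 lower) for genes with a mean above 5 TPM and to 190 (57 higher, 133 lower) for protein-coding rows, where 11823 and 13476 genes were tested. It was 70 with median-of-ratios scaling and 83 with upper quartile scaling. The labels do not say that replicate numbers pair the samples. Across genes, deviations of replicate 1 from the mean of its fraction correlated at 0.0719 between the fractions. Those of replicate 2 mirror them and add nothing. With the replicate block the count was 596 (228 higher, 368 lower). With each library left out it ranged from 18 to 65, with 10 to 36 higher and 1 to 48 lower, and lower calls outnumbered higher ones except without either GFP-negative library (17 higher and 1 lower without replicate 1, 36 and 29 without replicate 2), in fits that assume the lone library varies like the other fraction. Of the 9 lists called, 0 stayed called with an estimated correlation and 0 by fry (smallest adjusted p 0.0682), 7 without GFP-positive replicate 1, 7 without GFP-negative replicate 2 and all 9 in the other settings. With the replicate block the added calls were hematopoietic transcription factors (camera adjusted p = 0.0318), cell cycle genes (0.0134) and glycolysis genes (0.0454). Calls lost with an estimated correlation included lists estimated below the preset, such as arterial genes (-0.0169). The cause of these shifts was not tested. Tests and filters that need read counts were planned and not run. Without the shallowest GFP-positive library, replicate 2, 53 genes passed; depth was not tested otherwise.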

Other observations

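All tests of explanations in this part were chosen after the results were seen, as were the genes named in it. Genes outside the fixed lists also differed between the fractions. H19, an imprinted non-coding RNA, rose from 54.4 to 328 TPM in GFP-positive cells (log2 fold change 2.59 ± 0.21, SE, n = 2 per fraction; limma adjusted p = 0.0316). Its neighbour IGF2, a fetal growth factor gene, had 126 against 45.6 TPM and did not pass (limma adjusted p = 0.058). MYL4, an embryonic and atrial myosin light chain gene, rose from 86.0 to 339 TPM, the metallothionein gene MT2A from 139 to 469 TPM and BEX1 from 190 to 600.3 TPM (limma adjusted p = 0.0316 for each). Lower in GFP-positive cells were KITLG, the gene of the ligand of KIT, from 119 to 26.5 TPM (limma adjusted p = 0.0439), IGFBP2, an insulin-like growth factor binding protein gene, from 1651 to 717 TPM, the spectrin gene SPTAN1 from 246 to 58.8 TPM and GAP43, a growth cone protein gene, from 181 to 52.9 TPM (limma adjusted p = 0.0316 for each). Without GFP-negative replicate 1, limma gave BEX1 0.0664, KITLG 0.102, IGFBP2 0.093, SPTAN1 0.0519 and GAP43 0.108; without GFP-negative replicate 2, KITLG had 0.0801, and without GFP-positive replicate 1, IGFBP2 had 0.0542.

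The pan-endothelial genes were lower in GFP-positive cells by very unequal amounts. Cells with none of these transcripts in the GFP-positive fraction would lower every such gene alike. Over the 35 genes with at least 20 TPM in GFP-negative cells, the variance of the log2 fold changes was 13.9 times their mean squared SE. This is above a chi-square limit of 1.53, which takes genes as independent, while the list's estimated correlation was 0.174. It argues only against dilution by cells with none of these transcripts as the whole cause. Cells with some of them would lower the genes unequally, and dilution by such cells was not tested. ERG and TAL1 are also on the hematopoietic transcription factor list, and VWF is on the megakaryocyte list. The shallowest GFP-positive library, replicate 2, is also argued against as the sole source, since the list's median was -1.05 without it. Mesenchymal and smooth muscle genes had a median of 0.40 and were called higher in some settings only. A candidate explanation that stays open is a lower endothelial programme in the cells with the reporter, which no test here separates from other differences between the sorted cells.

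Erythroid genes, with a median log2 fold change of 2.22, were higher in cells sorted to lack CD43. Whether blood cells of mixed lineages escaped the gate cannot be told apart from a difference between the sorted cells: the 13 measured myeloid genes had a median of -0.0913, but 10 of them lay below 10 TPM in both fractions, and the median ran from -0.22 without GFP-positive replicate 2 to 0.33 with a mean above 5 TPM. The pan-leukocyte gene PTPRC had 1.19 against 1.48 TPM (log2 fold change -0.06 ± 0.71, SE) in GFP-positive and GFP-negative cells. MPO had 0.295 against 0 TPM and CD14 0 against 0.35 TPM. These genes lay near the floor and do not decide the question. LYZ, of the myeloid list, had 14.5 against 10.1 TPM, and the transcription factor gene SPI1 39.1 against 11.6 TPM (limma adjusted p = 0.588 and 0.132). Of the 13 myeloid genes, 6 were above 0 and 7 below. The level that a share of such cells would need is not known here. Erythroid or megakaryocytic cells with CD43 also remain open, since SPN, with a log2 fold change of 0.32, had a level of 10.4 TPM in GFP-negative cells that would hide a small share of such cells. HBE1 at 113 and 36.1 TPM and HBG2 at 90.6 and 45.7 TPM were the most abundant globin genes in the GFP-positive libraries. The HBG2 values rest on its split from the near-identical HBG1, which is uncertain.

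Rows at 10 TPM or more in both libraries of a fraction and at 0 in both of the other numbered 20. The 2 other ways to halve the libraries gave up to 25 such rows, so this count is consistent with scattered detection of short transcripts unrelated to the fraction. Differences of single rows of this kind, though past the threshold in limma, may not reflect the sort.

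Genes past the threshold numbered 69 in the real grouping and at most 1 in the 2 other splits of the 4 libraries; 1 of 3 splits gave as many, and 3 splits are too few for a share under 0.05. The 18 measured imprinted genes other than H19, 11 higher and 7 lower, were not called by camera (median log2 fold change 0.11; adjusted p = 0.439). The 6 measured metallothionein genes other than MT2A, 5 of them higher, had a median of 1.38 and were not called either (camera adjusted p = 0.0725).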
